A study of Mus musculus with 32 samples.

How the data were processed

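RNA sequencing libraries were made from sorted mouse embryonic stem cells of the CAST/129 F1 lines S2TG and M2TG. There were 16 libraries per line in 8 groups of 4 replicates, each group being 1 line and 1 gate of tdTomato (T) and eGFP (G) fluorescence. Per the labels' protocols, cells grew in serum and LIF on mouse embryonic fibroblast feeders, were plated on gelatin to remove feeders and were sorted, 0.5 M cells per library (M, mega). Per the same protocols, libraries were stranded and made with KAPA HyperPrep for S2TG and TruSeq for M2TG, so the kit cannot be told apart from the line. Per the submitters' processing notes, STAR 2.5.3, RSEM 1.2.31, DESeq2 1.18.1 and the build mm10 were used. Which step used which, the annotation version and whether the counting used strand are not given in the sources used here. The strain of the feeders is not given either.

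For each library the authors deposited 4 gene tables in RSEM layout, for reads assigned to genome1, to genome2, to neither (unassigned) and to both in conflict, 128 tables in all. Each holds 37227 entries, of which 37224 carry Ensembl gene numbers and 3 are the submitters' own (eGFP, tdTomato and an entry of 3216 bases taken by its name as the miR-290 primary transcript). Which parent is genome1 is not given in the sources used here, and the position of the miR-290 entry is not given either. Per the file headers, the values are RSEM expected counts, which need not be whole, together with TPM and FPKM. The deposited expected counts are the unit analysed. The deposited FPKM values of genome1 and genome2 served only in an alternative for allele shares, and the TPM values were not used. Gene symbols and positions came from the GENCODE M21 annotation of mm10, in which 35449 gene numbers were found.

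The count of a gene was the sum of its genome1, genome2 and unassigned expected counts, rounded to whole numbers. Conflicting reads, at most 0.079% of a library, were left out. Allele-assigned reads made up 32.3 to 35.7% of the counts and genome1 gave 42.3 to 45.5% of these. The 10 most abundant genes took 5.59 to 7.48% of the counts in S2TG libraries and 6.28 to 7.25% in M2TG libraries, and the reporters at most 0.106%. Depth ran from 4.73 to 14.94 M counts, which sets the counting error of each value. No pair of replicates was a copy: over the 48 pairs within groups, the chi-square per degree of freedom of genes with at least 20 counts lay between 4.85 and 47.3.

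The following choices were made before the data were examined. Each line was fitted on its own with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by group, robust quasi-likelihood F test, gate as the only term, all 16 libraries), with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were T-G- against T+G+, T+G- against T-G+, and each of T+G- and T-G+ against T+G+. A fit of all 32 libraries tested whether the T-G- against T+G+ change differed between lines. The allelic test compared the genome1 to genome2 ratio between T+G- and T-G+ with 2 columns per library and a term for each library, for genes with a mean of at least 20 allele-assigned counts. Shares of genome1 in percent at Sox2 and the miR-290 entry were compared by a 2-sided exact permutation test, whose smallest p with 4 against 4 is 0.0286.

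Gene lists were fixed at the same time: general and naive pluripotency, formative and primed, primitive endoderm, primitive streak and mesoderm, neuroectoderm, trophectoderm, 2-cell-like, fibroblast feeder, DNA methylation enzymes, germline genes silenced by methylation, imprinted genes, miR-290 family targets, neighbours at the miR-290 locus, responses to FGF-ERK, LIF-STAT3, BMP-SMAD, Nodal-Activin and WNT, immediate early and heat shock, p53 response, G1-S and G2-M cell cycle, housekeeping, and blood, endothelial and immune genes. These 25 lists held 417 symbols, 405 of them in the files. Camera (limma 3.58.1) tested each list with at least 5 tested members with a preset correlation between genes of 0.01, and again with an estimated correlation. The self-contained test fry was an alternative.

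The genes named were chosen by this rule. In T-G- against T+G+ cells of each line, genes past the threshold with a mean of at least 5 CPM and no overlap between the 4 T-G- and the 4 T+G+ libraries were ranked, leaving out predicted, Rik and pseudogene symbols, and the 10 largest rises and 10 largest falls were taken. The 4 members of each list with the smallest p, Sox2 and the miR-290 locus were added, of which the text gives a part. For the line difference the rule took the 5 largest differences in each direction, reading the overlap condition as same-numbered differences of the lines that do not overlap, a reading made after the data were seen. For the allelic contrast it took the 10 genes with the smallest adjusted p, Sox2, the miR-290 locus and the imprinted genes as a group. Genes outside the rule are said to be named after their values were seen.

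Replicate numbers in the labels are shared by the gates. After removal of the gate means, libraries with the same number correlated at 0.18 to 0.74 (median 0.49) in S2TG and 0.56 to 0.86 (median 0.66) in M2TG, against medians of -0.16 and -0.25 for other numbers, and each of the 16 libraries of each line correlated best with libraries of its own number. The numbers therefore pair the libraries, and a fit with the number as a block was computed for each result. The pairing comes from the shared numbers and these correlations; the labels do not say that a number marks a shared culture or day. In a principal component analysis of M2TG, replicate 1 stood apart in every gate (first component -58.8 to -56.7 against 11.9 to 26.6 for the other libraries).

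The scripts were tested on simulated data. For T-G- against T+G+ in S2TG, with 12835 genes of which 200 were changed, the test recovered 19% of changes of 1.5-fold, 66.2% of 2-fold and 89.9% of 4-fold with 7 false calls; in M2TG, with 13299 genes, it recovered 20.3, 56.5 and 74.6% with 5 false calls. It made 0 calls in an unchanged contrast. The allelic test, on 9276 S2TG genes, recovered 69.5% of shifts of 15 percentage points with 8 false calls. The simulated libraries had no structure by replicate number, and the simulated allele shares varied by counting error alone. These rates therefore need not hold for the real libraries.

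Alternatives set at the start were DESeq2 1.42.0, RLE normalization, no low-count filter or at least 5 CPM in at least 4 libraries, conflicting reads added, genome1 or genome2 reads alone, a 2-fold minimum (1 on the log2 scale), the replicate block, the fibroblast list score as a covariate, a fit of only the 8 libraries compared, a fit of all 32 libraries, allele count minimums of 5 and 100, FPKM in place of counts for shares, and leaving out each library. Added after the data were seen were fits without the reporter entries, without chromosome 6 or 8 genes, without all libraries of a replicate number, and with the block combined with other settings. The reporter entries stay in the main tests. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and plots with matplotlib 3.10.9. Reads, alignments and the authors' own differential tests were not analysed here.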

Results

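The libraries measured polyadenylated RNA in mouse embryonic stem cells of a cross between the CAST and 129 strains, in which a read that covers a strain difference can be assigned to 1 parental genome. A pair of lines was used, each carrying the fluorescent reporters tdTomato (T) and eGFP (G). S2TG is named for the super-enhancer, a dense cluster of enhancers, of Sox2, which encodes a core pluripotency transcription factor. M2TG is named for the super-enhancer of miR-290, a microRNA cluster abundant in mouse embryonic stem cells. Flow cytometry separated each line into 4 gates: both reporters on (T+G+), tdTomato alone (T+G-), eGFP alone (T-G+) and neither (T-G-). There were 4 libraries per gate and 32 libraries in all. The series title asks whether changing DNA methylation of enhancers underlies differences between cells. The comparisons ask how transcription differed between cells with both, 1 or neither reporter on. Total gene counts in units of M (mega) ran from 4.73 to 14.94 M per library with a median of 7.43 M. They ran from 4.87 to 14.94 M in S2TG and from 4.73 to 11.05 M in M2TG. Levels are CPM, counts scaled to library size, given as mean ± SD over n = 4 libraries per gate unless another n is named. Positions are on mm10. The labels describe 2 independently targeted clones per line with 2 sorts of each and do not say which replicate number is which. The p-values therefore measure the spread between such libraries and not between independent clones. In the edgeR fits this spread is estimated per gene over all groups of the fit, not from the gates compared alone.

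The reporter transcripts followed the gates in both lines. In S2TG, eGFP was at 188 ± 4.89 CPM in T+G+ and 198 ± 8.01 CPM in T-G+ cells, against 2.87 ± 3.58 CPM in T+G- and 1.41 ± 1.17 CPM in T-G- cells. S2TG tdTomato was at 411 ± 22.9 CPM in T+G+ and 426 ± 36.9 CPM in T+G- cells, against 7.67 ± 4 CPM in T-G+ and 2.62 ± 2.27 CPM in T-G- cells. In M2TG, eGFP was at 336 ± 74.5 and 349 ± 87.9 CPM in the 2 gates sorted as G+, against 7.85 ± 8.51 and 6.66 ± 8.24 CPM in the 2 sorted as G-. M2TG tdTomato was at 429 ± 138 and 461 ± 146 CPM in the T+ gates, 27.3 ± 39.5 CPM in T-G+ and 11.8 ± 12.6 CPM in T-G- cells, where the T-G+ mean rests on replicate 1 at 86.5 CPM. The 8 on-gate libraries lay above the 8 off-gate libraries for each reporter and line (2-sided exact permutation test, p = 0.000155 in each of the 4 cases, the smallest this test can give). The cells were sorted on these reporters, so this checks the sort only. The test also treats the libraries as independent, although the gates share replicate numbers.

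**Figure D1:**
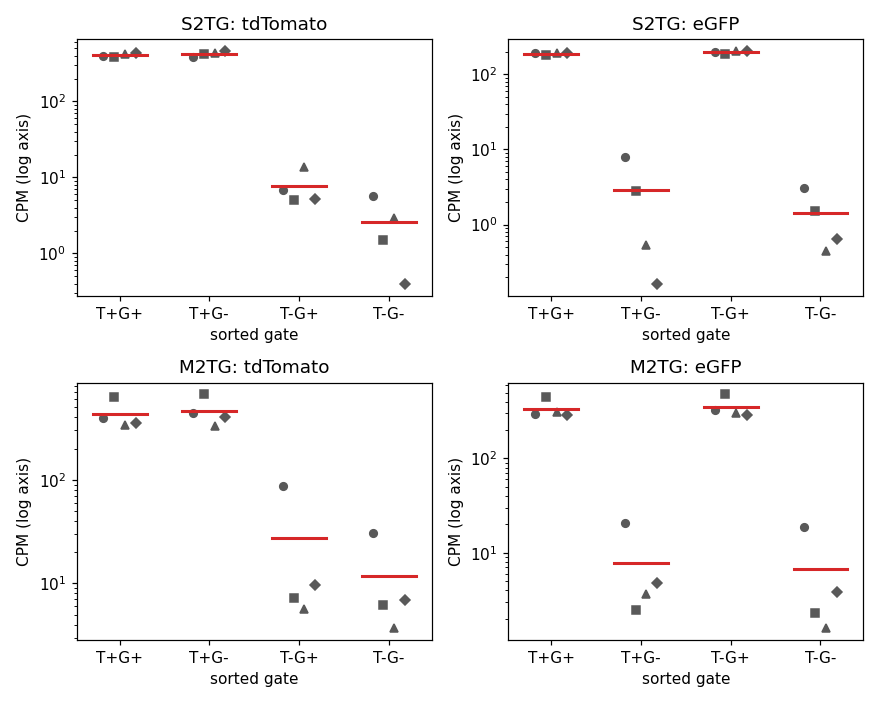
Reporter transcripts in CPM on a log axis for each gate of S2TG and M2TG. Each marker is 1 library (circle, square, triangle and diamond for replicates 1 to 4) and the red line is the gate mean; the lowest S2TG on-gate eGFP library is at 180.9 CPM and the highest off-gate one at 7.9 CPM.

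Pluripotency genes were lower in S2TG cells that had lost both reporters. Sox2 (chromosome 3, 34650405 to 34652461) fell from 365 ± 33.5 CPM in T+G+ to 152 ± 93.6 CPM in T-G- cells, 2.42-fold lower (log2 -1.27, SE 0.31, edgeR adjusted p = 0.0139). Of 18 naive pluripotency genes tested, 12 fell, 0 rose and 6 did not pass. The falls included the nuclear receptors Esrrb (log2 -1.09, SE 0.29) and Nr5a2 (log2 -1.32, SE 0.31), the homeobox factor Nanog (log2 -0.54, SE 0.12) and Tcl1, an AKT coactivator (56 ± 9.98 to 18.9 ± 13.7 CPM, log2 -1.60, SE 0.36). Of 15 general pluripotency genes, 4 fell and 11 did not pass. The falls included Pou5f1, which encodes OCT4 (log2 -0.63, SE 0.20, adjusted p = 0.0457), and the TGF-beta family ligand Gdf3 (log2 -0.96, SE 0.28). Counts adjusted over the list alone were 17 naive genes lower, 9 general pluripotency genes lower and 1 higher. With the replicate block 17 naive genes fell, and 11 general pluripotency genes fell and 2 rose. Camera placed both lists below other genes (adjusted p = 4.955e-11 and 0.00045). Both calls were lost with adjusted p = 0.182 and 0.211 with an estimated correlation. The T-G- libraries were not alike: Sox2 was at 262, 197, 67.6 and 80.7 CPM in replicates 1 to 4, against 333 to 400.1 CPM in the T+G+ libraries. Pou5f1 lost its call without any 1 of the 4 T+G+ libraries or T-G- replicate 2, 3 or 4 (adjusted p = 0.0532 to 0.14). Gdf3 lost it without T+G+ replicate 3 or 4 or T-G- replicate 3 or 4 (adjusted p = 0.055 to 0.0955), and Esrrb without T-G- replicate 3 or 4 (adjusted p = 0.0505 to 0.063).

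Markers of differentiating lineages rose in the same S2TG cells. Of 7 primitive streak and mesoderm genes tested, 6 rose and 1 did not pass. The growth factor Fgf8 rose by 6.81 on the log2 scale, the ligand Wnt3 by 4.42 (SE 0.70), the T-box factor T, also called brachyury, by 4.34 (SE 0.89, 5.45 ± 4.26 to 105 ± 80.3 CPM) and Eomes by 2.65 (SE 0.47). Of 13 primitive endoderm genes, 10 rose and 3 did not pass, with the GATA factor Gata4 at log2 3.34 (SE 0.53) and the receptor Pdgfra at log2 4.09 (SE 0.71). Of 10 trophectoderm genes, 5 rose and 5 did not pass. Among the rises were the epithelial keratins Krt8 (chromosome 15, 101996698 to 102004482; 11.8 ± 5.25 to 468 ± 404 CPM, log2 5.33, SE 0.74) and Krt18 (log2 4.52, SE 0.69). Of 18 formative and primed genes, 8 rose and 10 did not pass. The rises included Fgf5, a marker of postimplantation epiblast (chromosome 5, 98254184 to 98277030; log2 4.83, SE 0.84), the POU factor Pou3f1 (log2 2.36, SE 0.44) and N-cadherin, Cdh2 (log2 3.27, SE 0.51). Of 9 neuroectoderm genes, 2 rose and 7 did not pass, one of the rises being the intermediate filament gene Nes (log2 2.07, SE 0.40). In tests adjusted over the list alone, 6 streak, 10 primitive endoderm and 5 trophectoderm genes rose, 9 formative genes rose and 2 fell, and 2 neuroectoderm genes rose and 1 fell. The replicate block called 7 streak, 11 primitive endoderm and 5 trophectoderm genes higher, 10 formative genes higher and 3 lower, and 2 neuroectoderm genes higher and 2 lower. Camera adjusted p-values were 1.449e-05 for the streak, 4.517e-06 for primitive endoderm, 0.00283 for trophectoderm, 0.00776 for formative (0.053 with the replicate block) and 0.795 for neuroectoderm genes. With an estimated correlation the first 4 became adjusted p = 0.182, 0.192, 0.182 and 0.211. In T-G- replicate 1 these markers lay near the T+G+ libraries: T was at 3.43, 138, 84.5 and 192 CPM in T-G- replicates 1 to 4 against 1.65 to 10.7 CPM in T+G+, and Krt8 at 35.1, 269, 605 and 961 CPM against 7.65 to 19.4 CPM.

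Fibroblast and imprinted genes also rose in S2TG T-G- cells. The feeder layer named in the labels is made of mouse embryonic fibroblasts. Of 24 fibroblast genes tested, 10 rose and 14 did not pass. The actin-binding gene Tagln was at log2 4.27 (SE 0.73, 8.42 ± 3.93 to 159 ± 123 CPM), the smooth muscle actin gene Acta2 at log2 3.74 (SE 0.76) and the collagen Col5a1 at log2 3.17 (SE 0.62). Of 19 imprinted genes, 6 rose and 13 did not pass. The fetal growth factor Igf2 rose from 8.58 ± 2.78 to 165 ± 67.6 CPM (log2 4.30, SE 0.47), Peg10 from 774 ± 148 to 2448 ± 1028 CPM (log2 1.66, SE 0.25), its neighbour Sgce by 2.17 on the log2 scale (SE 0.34) and Peg3 by 1.12 (SE 0.25). Adjusted over the list alone, 15 fibroblast genes rose and 1 fell, and 7 imprinted genes rose. With the block 18 fibroblast genes rose and 1 fell, and 10 imprinted genes rose and 2 fell. Camera gave adjusted p = 4.517e-06 for the fibroblast and 0.0017 for the imprinted list. Both calls were lost with adjusted p = 0.286 and 0.182 with an estimated correlation. Tagln was at 11.3, 102, 259.1 and 262 CPM in T-G- replicates 1 to 4, and replicate 1, the lowest for Tagln, was also the lowest for T and Krt8 and the highest for Sox2. Igf2 was at 64.4, 183, 206 and 205 CPM.

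**Figure D2:**
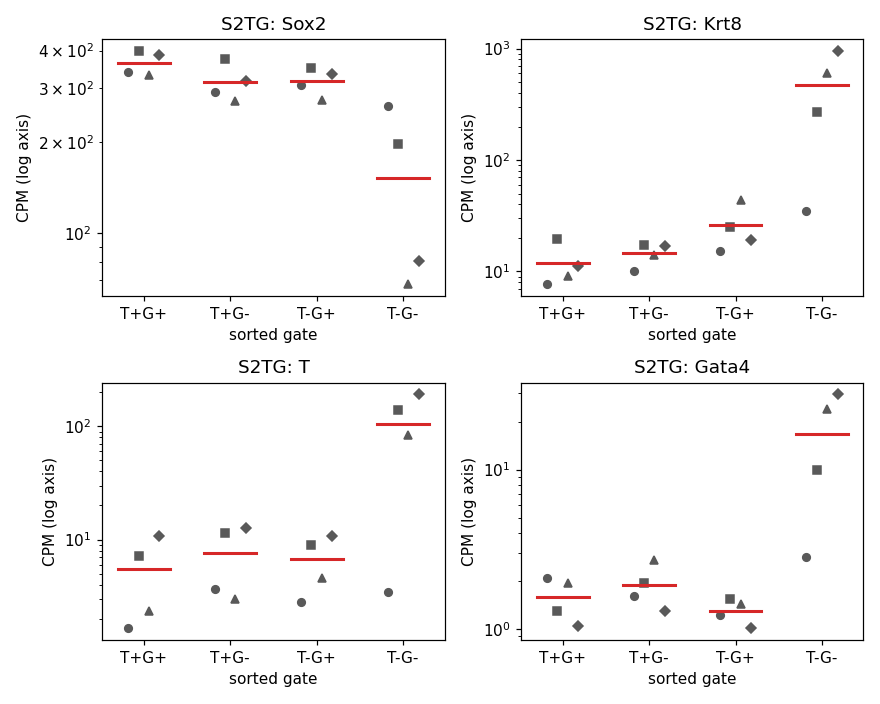
CPM of genes from the named groups in each S2TG library, by gate, on a log axis. Markers are replicates 1 to 4 (circle, square, triangle, diamond) and red lines gate means; in T-G- cells, Sox2 ranges from 67.6 to 262 CPM and Krt8 from 35.1 to 961 CPM.

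Signalling and cell cycle lists moved in both directions in S2TG T-G- cells. Of 9 Nodal-Activin response genes, 4 rose and 5 did not pass. The rises included Nodal (log2 0.74, SE 0.25, adjusted p = 0.0492) and the feedback inhibitor Pmepa1 (log2 1.67, SE 0.38). The largest rise in this list was log2 6.81, the value of Fgf8 in the streak list. Lists may thus share members, and their results are not independent. Of 12 LIF-STAT3 response genes, 2 fell and 10 did not pass, one fall being Klf5 (log2 -0.77, SE 0.18). Of 17 G1-S genes, 8 fell and 9 did not pass, with the replication helicase subunits Mcm3 (log2 -0.40, SE 0.09) and Mcm6 (log2 -0.33, SE 0.08). Of 17 G2-M genes, 3 fell, 1 rose and 13 did not pass, with cyclin B1, Ccnb1, lower (log2 -0.45, SE 0.10) and the proliferation marker Mki67 higher (log2 0.27, SE 0.09). Of 18 germline genes known to be silenced by DNA methylation, 2 fell, Tex19.1 (log2 -0.81, SE 0.24) and Tex19.2 (log2 -1.39, SE 0.35), and 16 did not pass. Tex19.2 was low throughout, at 1.4 to 2.26 CPM in T+G+ and 0.56 to 1.04 CPM in T-G- libraries. Of 15 DNA methylation enzymes and readers, the methyl-CpG binding gene Mbd2 rose (log2 0.65, SE 0.15), Uhrf1, which recruits the maintenance methyltransferase, fell (log2 -0.47, SE 0.10) and 13 did not pass. Of 18 predicted or known targets of the miR-290 family, 8 rose, 1 fell and 9 did not pass. The rises included the Hippo kinase Lats2 (log2 3.25, SE 0.71) and Rhoc (log2 1.22, SE 0.27), and the fall was Ei24 (log2 -0.59, SE 0.12). With p adjusted over the list alone, 7 Nodal-Activin genes rose, and 3 LIF-STAT3, 9 G1-S and 2 germline genes fell. Among G2-M genes 6 fell and 1 rose, among methylation genes 1 rose and 1 fell, and among miR-290 targets 10 rose and 1 fell. The block called more members: 13 germline and 12 G1-S genes fell, 10 G2-M genes fell and 1 rose, and 4 methylation genes rose and 6 fell. It also called 7 Nodal-Activin genes higher and 1 lower, 2 LIF-STAT3 genes higher and 6 lower, and 12 miR-290 targets higher and 2 lower. Camera adjusted p-values were 0.00209 for Nodal-Activin, 0.0288 for LIF-STAT3 (0.0755 with the replicate block), 0.000139 for G1-S, 0.0221 for G2-M, 5.117e-05 for germline, 0.526 for methylation and 0.011 for miR-290 target genes. With an estimated correlation these became adjusted p = 0.182 for Nodal-Activin, 0.211 for LIF-STAT3, G1-S and germline, 0.332 for G2-M and 0.315 for miR-290 target genes. Mcm3 was at 468, 430.4, 342 and 361 CPM in T-G- replicates 1 to 4 and Tex19.1 at 68.4, 43.8, 27.1 and 26.3 CPM. Replicate 1 lay nearest the T+G+ libraries (487 to 569 CPM and 64.6 to 89.3 CPM) here too. Nodal (adjusted p = 0.065 to 0.205) and Mki67 (adjusted p = 0.0636 to 0.181) lost their calls without any 1 T+G+ library or T-G- replicate 3 or 4. Tex19.1 lost it without T+G+ replicate 2 or 4 or T-G- replicate 3 or 4 (adjusted p = 0.0529 to 0.101), and Tex19.2 (adjusted p = 0.06) and Mbd2 (adjusted p = 0.0526) without T-G- replicate 3.

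The other lists were mixed in S2TG T-G- cells. Of 14 immediate early and heat shock genes, 3 rose, 1 fell and 10 did not pass, with the AP-1 subunit Jun at log2 3.44 (SE 0.79). Of 12 p53 response genes, 3 rose and 9 did not pass, including the membrane protein gene Perp (log2 2.63, SE 0.43). Of 12 FGF-ERK response genes, 2 rose and 10 did not pass, including the ERK phosphatase Dusp6 (log2 1.65, SE 0.29). In the BMP-SMAD list 1 gene rose and 9 did not pass, in the WNT list 2 rose and 9 did not pass, and in the 2-cell-like list 0 of 8 passed by edgeR. Of 5 blood, endothelial and immune genes, the angiopoietin receptor Tek fell (log2 -1.10, SE 0.32) and 4 did not pass. Of 15 housekeeping genes, 1 rose, the class I antigen light chain B2m (log2 2.79, SE 0.51), 1 fell and 13 did not pass. When adjusted over the list alone, 3 immediate early genes rose and 1 fell, 3 p53 genes rose, 2 FGF-ERK genes rose and 1 fell, and 1 BMP-SMAD gene rose and 1 fell. By the same adjustment 2 WNT genes rose, 0 genes of the 2-cell-like list passed, 1 blood gene fell and 1 housekeeping gene rose. With the block 8 immediate early genes rose and 2 fell, 7 p53 genes rose and 2 fell, 6 FGF-ERK genes rose and 3 fell, and 5 BMP-SMAD genes rose and 1 fell. In the same fit 4 WNT genes rose and 3 fell, 4 of the 2-cell-like list and 3 blood genes fell, and 4 housekeeping genes rose and 3 fell. Camera adjusted p was 0.0307 for blood (0.0592 with the replicate block and 0.211 with an estimated correlation). It was 0.245 for immediate early (0.0011 with the block) and for BMP-SMAD, 0.249 for p53, 0.197 for FGF-ERK, 0.614 for WNT, 0.163 for 2-cell-like (0.048 with the block) and 0.759 for housekeeping genes. With the block and an estimated correlation, the immediate early and 2-cell-like calls were lost (adjusted p = 0.255 and 0.3865). The housekeeping list had a median of 0.03 and a mean of 0.16 while camera's direction was down. At the miR-290 locus, where 3 annotated neighbours could be tested and camera was not run, Myadm rose (log2 0.79, adjusted p = 0.0388) and AU018091 and Nlrp12 did not pass (log2 -0.71 and -0.81). AU018091 passed with the replicate block (block log2 -0.81, adjusted p = 0.0315). Adjusted over the list alone, 1 of these neighbours rose and 1 fell. The entry taken by its name as the miR-290 primary transcript was at log2 -0.73 (SE 0.50, adjusted p = 0.309). Jun was at 11.5, 43, 253 and 230 CPM and Dusp6 at 30.7, 69.4, 127 and 112 CPM in T-G- replicates 1 to 4. Tek lost its call without T+G+ replicate 3 or 4 or T-G- replicate 3 or 4 (adjusted p = 0.054 to 0.0962).

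Across all genes, T-G- and T+G+ cells of S2TG differed at 2283 of 12979 entries, 1597 higher and 686 lower in T-G- cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Of these, 915 and 151 changed at least 2-fold. Of the 35 splits of these 8 libraries, 2 called as many, the other one parting 2 of the 4 replicate numbers. Among genes whose 4 T-G- and 4 T+G+ libraries did not overlap, the largest rises by the naming rule were the protocadherin Pcdh7 (log2 6.93, SE 1.07), the interferon-induced GTPase Gbp2 (3.21 ± 0.51 to 180 ± 147 CPM, log2 5.84, SE 0.76), Krt8 and the coagulation factor gene F5 (log2 5.07, SE 0.70). Next came the immunoproteasome subunit Psmb8 (log2 4.98, SE 0.69), Fgf5, the hyaluronan receptor Cd44 (log2 4.61, SE 0.85), the carbonic anhydrase Car4 (log2 4.61, SE 0.78), Zfp703 (log2 4.56, SE 0.78) and the cytokine gene Csf1 (log2 4.55, SE 0.79). By the same rule the largest falls were Lrrc31 (log2 -2.03, SE 0.36), Zmat4 (log2 -2.02, SE 0.45), Sh2d4b (log2 -1.82), Usp26 (log2 -1.70), Nexmif (log2 -1.69), the urothelial gene Upk1a (log2 -1.64), the water channel Aqp3 (log2 -1.64), Elobl (log2 -1.62), Tcl1 and Pgc (log2 -1.58). DESeq2 called 3049 entries. The replicate block called 6021, 3158 higher and 2863 lower, and these held the 2283. The number of S2TG double negative vs double positive genes (T-G- against T+G+) rested on few libraries. Removing T-G- replicate 1 raised it to 4954, and removing T-G- replicate 3, T-G- replicate 4 or T+G+ replicate 4 lowered it to 873, 864 or 1478. Without all libraries of replicate number 1 it was 4145, and without number 2, 3 or 4 it was 2, 4 or 3. The entries left were the reporters, Igf2 (without number 3 or 4) and Nrk (without number 3). Nrk is named after its values were seen. A fit of only the 8 libraries compared, or one with the fibroblast list score as a covariate, called 3 entries, the reporters and Igf2. The main fit pools the spread over all 4 gates, and the T-G- libraries were spread widest. On the first principal component they lay at -16.5 to 91.9 and the other gates at -28.6 to 2.4. The main p-values may thus be too small for T-G- cells, while the smaller fit has fewer libraries to estimate the spread. Of 71 named genes other than Sox2 that passed, 15 lost their call without T-G- replicate 3, 13 without T-G- replicate 4, 10 without T+G+ replicate 4 and 70 with the fibroblast score. In genome1 reads 7 of 48 lost it, and in genome2 reads 15 of 56. The score is the mean level of the fibroblast list in these same libraries, and that list rose in T-G- cells. The covariate therefore takes out changes that run with the list whatever their source, and these losses do not show that feeders caused the calls. Among the falls, Aqp3 lost its call without T+G+ replicate 3 or 4 or T-G- replicate 2, 3 or 4 (adjusted p = 0.0583 to 0.118). Nexmif lost it without T+G+ replicate 2 or 4 or T-G- replicate 3 or 4 (adjusted p = 0.0594 to 0.0911), Upk1a without T-G- replicate 4 (adjusted p = 0.0551) and Elobl without T-G- replicate 3 (adjusted p = 0.0548). Sox2 passed without any 1 library of these gates and lost its call with the fibroblast score (log2 -0.76, adjusted p = 0.353) and in genome2 reads alone (log2 -0.84, adjusted p = 0.116).

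In S2TG no gene other than the reporters passed without the replicate block between gates with at least 1 reporter on. T+G- against T-G+ gave 2 calls, eGFP and tdTomato, T+G- against T+G+ gave eGFP and T-G+ against T+G+ gave tdTomato. By edgeR 0 other entries passed. At an unadjusted p under 0.05 there were 65, 106 and 101 entries, and DESeq2 called the same numbers, 2, 1 and 1. With the replicate block the amino acid transporter Slc7a3, named after its values were seen, was lower in T+G- than in T+G+ cells (block log2 -0.66, block adjusted p = 0.00764). Sox2 lay at 314 ± 44.4 CPM in T+G- and 317 ± 33.6 CPM in T-G+ cells. The fibroblast list was higher in T-G+ than in T+G+ cells by camera (adjusted p = 6.22e-34, median log2 1.39; adjusted p = 0.0765 with an estimated correlation). It had 0 members past the test over all genes and 11 rises adjusted over the list alone. It was lower in T+G- than in T-G+ cells (adjusted p = 1.165e-19, median log2 -1.10; adjusted p = 0.195 with an estimated correlation). It was higher in T+G- than in T+G+ cells (adjusted p = 0.0248, 0.0761 with the replicate block; adjusted p = 0.972 with an estimated correlation). In both, no member passed adjusted over the list alone. Tagln was at 8.42 ± 3.93 CPM in T+G+, 10 ± 5.09 CPM in T+G- and 16.7 ± 7.99 CPM in T-G+ cells. In T-G+ replicates 1 to 4 Tagln was at 13.86, 10.36, 28.43 and 14.28 CPM and Col5a1 at 47.9, 21.05, 86.39 and 23.35 CPM. Replicate 3 was the highest for both genes. In that library genome1 gave 42.33% of all allele-assigned counts, against 43.01, 42.85 and 43.18% in the T+G+, T+G- and T-G- libraries of replicate 3. Whether feeder reads gave the rise of the list in T-G+ cells was not tested. Camera also placed neuroectoderm genes lower in T+G- cells, against T-G+ (adjusted p = 0.0157; adjusted p = 0.141 with an estimated correlation) and against T+G+ (adjusted p = 0.00685; adjusted p = 0.082 with an estimated correlation). Against T+G+, streak genes were higher in T+G- (adjusted p = 0.00685) and in T-G+ cells (adjusted p = 0.0305), Nodal-Activin genes in T+G- cells (adjusted p = 0.0379) and trophectoderm genes in T-G+ cells (adjusted p = 0.0305, 0.0717 with the replicate block). With an estimated correlation these became adjusted p = 0.658, 0.899, 0.658 and 0.409. The block added miR-290 targets in T-G+ against T+G+ cells (adjusted p = 0.0188; 0.252 with an estimated correlation as well). No other list passed in these 3 comparisons without the block.

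In M2TG, the test without the replicate block separated few genes of T-G- and T+G+ cells, 17 entries against 3185 with the block. Sox2 lay at 441 ± 73.4 CPM in T+G+ and 454 ± 81.5 CPM in T-G- cells (log2 0.04, SE 0.16, adjusted p = 0.9999). The genes that rose in T-G- cells included Mbp, which encodes myelin basic protein (8.05 ± 1.44 to 17.4 ± 0.0557 CPM, log2 1.11, SE 0.15, adjusted p = 0.0074), the actin bundler Pls3 (log2 1.05, SE 0.17, adjusted p = 0.0199), the glutathione transferase Gstm2 (log2 0.80, SE 0.12, adjusted p = 0.0136), the interferon-induced membrane protein gene Ifitm1 (196 ± 26.6 to 325 ± 22.6 CPM, log2 0.73, SE 0.11, adjusted p = 0.0136). Smaller rises were those of Lrig1 (log2 0.50, SE 0.09, adjusted p = 0.0426) and Kctd10 (log2 0.50, SE 0.08, adjusted p = 0.0302). Those that fell included the bicarbonate transporter Slc4a5 (log2 -1.34, SE 0.22, adjusted p = 0.0199), Lrmp (log2 -1.03, SE 0.19, adjusted p = 0.0444) and the formin Fhod3 (log2 -0.69, SE 0.12, adjusted p = 0.0392). The guanine nucleotide exchange factor gene Mcf2 fell too (85.6 ± 6.26 to 54.7 ± 2.15 CPM, log2 -0.65, SE 0.08, adjusted p = 0.00428), as did Zfp992 (log2 -0.61, SE 0.09, adjusted p = 0.0136). All 4 T-G- libraries lay above the 4 T+G+ libraries for Mbp (17.4 to 17.5 against 6.73 to 9.33 CPM) and below them for Mcf2 (52.3 to 57.5 against 78.5 to 93.8 CPM).

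The test called 17 of 13445 entries in M2TG T-G- against T+G+ cells, 9 higher and 8 lower, of which 2 were the reporters (edgeR). At an unadjusted p under 0.05 there were 864 entries, and DESeq2 called 124. The replicate block called 3185, 1606 higher and 1579 lower, with a median absolute log2 change of 0.29, and these held the 17. The count was 5 without T+G+ replicate 3, 4 without T+G+ replicate 4, 4 without T-G- replicate 2 and 4 without T-G- replicate 4. Without all libraries of number 1 it was 37, and without number 2, 3 or 4 it was 3, 1 or 1. A fit of the 8 libraries compared called 1 entry, 9530068E07Rik, which is named after its values were seen. Of the 11 named genes, Mcf2 and Mbp passed without any 1 library of these gates. Of the others, 8 lost their call without T+G+ replicate 3, and 9 without T+G+ replicate 4, T-G- replicate 2 or T-G- replicate 4. The number was 4 without T+G+ replicate 1, T-G- replicate 1 or T-G- replicate 3, and 2 without T+G+ replicate 2. The adjusted p then lay between 0.0611 and 0.204 (Lrig1, Lrmp and Fhod3 reached the latter). With the fibroblast score 5 of the 11 lost their call, in genome1 reads 8 of 8 and in genome2 reads 9 of 10.

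No member of any list passed the test over all genes in M2TG T-G- against T+G+ cells (edgeR). Camera placed 5 of 24 lists past the threshold. Fibroblast genes were higher (24 tested, median log2 1.01, adjusted p = 1.484e-15; adjusted p = 0.181 with an estimated correlation). There were 10 rises adjusted over the list alone and 10 rises over all genes with the replicate block. Tagln was at 7.13 ± 0.774 CPM in T+G+ and 30.8 ± 16.8 CPM in T-G- cells (log2 2.11, SE 0.39, adjusted p = 0.0531; block log2 2.00, block adjusted p = 0.000623). It was at 40.8, 48.9, 13.4 and 20.2 CPM in T-G- replicates 1 to 4 and passed without replicate 3 (log2 2.36, adjusted p = 0.0248) and with DESeq2. G2-M genes were lower (17 tested, median log2 -0.21, adjusted p = 1.034e-06; adjusted p = 0.499 with an estimated correlation), with 2 falls adjusted over the list alone. Cdk1 was at log2 -0.47 (SE 0.12, adjusted p = 0.198) and Ccnb1 at log2 -0.28 (SE 0.07, adjusted p = 0.239), and both fell with the block and by DESeq2. Targets of the miR-290 family were higher (19 tested, median log2 0.22, adjusted p = 0.000776; adjusted p = 0.303 with an estimated correlation), with 1 rise adjusted over the list alone. Trophectoderm genes were higher (9 tested, median log2 0.37, adjusted p = 0.0296; adjusted p = 0.181 with an estimated correlation), with 2 rises adjusted over the list alone. Krt8 was at log2 1.40 (SE 0.48, adjusted p = 0.445, block adjusted p = 0.0217; log2 0.48 without T-G- replicate 2, which held 90.8 CPM), and Krt18 was at log2 0.85 (SE 0.29, adjusted p = 0.428, block adjusted p = 0.0348). G1-S genes were lower (17 tested, median log2 -0.08, adjusted p = 0.0387; adjusted p = 0.614 with an estimated correlation), with 0 falls adjusted over the list alone by edgeR. With the block 10 G2-M and 8 G1-S genes fell, 11 miR-290 targets rose, and 4 trophectoderm genes rose and 1 fell. Without T+G+ replicate 4, 3 lists passed.

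The other lists did not pass in M2TG T-G- against T+G+ cells without the replicate block. Camera adjusted p was 0.699 for general pluripotency, 0.782 for naive (0.036, lower, with the block), 0.346 for formative, 0.835 for primitive endoderm and 0.333 for streak genes. It was 0.203 for neuroectoderm (0.0281, higher, with the block), 0.782 for 2-cell-like and for methylation genes, 0.203 for germline (0.000127, lower, with the block) and 0.26 for imprinted genes. It was 0.0713 for FGF-ERK (0.000498, higher, with the block), 0.835 for LIF-STAT3, 0.458 for BMP-SMAD, 0.803 for Nodal-Activin and for housekeeping, 0.354 for WNT, 0.203 for immediate early, 0.915 for p53 and 0.749 for blood genes. With the block and an estimated correlation, the calls of the naive (adjusted p = 0.44), neuroectoderm (0.353), germline (0.162) and FGF-ERK (0.162) lists were lost. If adjusted over the list alone, 1 naive and 2 imprinted genes rose, 1 methylation gene rose and 1 fell, and 1 neighbour of the miR-290 locus rose. With the block, 4 naive genes rose and 8 fell, 2 general pluripotency genes rose and 6 fell, 1 germline gene rose and 10 fell, and 7 imprinted genes rose and 3 fell. It called 3 formative genes higher and 4 lower, 2 primitive endoderm genes lower, 1 streak, 3 neuroectoderm, 3 FGF-ERK and 2 WNT genes higher, and 2 methylation genes higher and 3 lower. The blocked fit also had 2 LIF-STAT3 genes higher and 2 lower, 1 BMP-SMAD gene higher and 2 lower, 3 Nodal-Activin genes higher and 3 lower, and 5 immediate early genes higher and 2 lower. Of p53 genes 2 rose and 2 fell, of housekeeping genes 1 rose and 3 fell, 1 blood gene rose and no 2-cell-like gene passed. Members that passed with the block included Dppa3, a factor protecting DNA methylation in the zygote (log2 0.73, SE 0.19, adjusted p = 0.212; called by DESeq2), Dusp6 (log2 0.82, SE 0.28, adjusted p = 0.435), Mbd2 (log2 0.49, SE 0.13, adjusted p = 0.244) and Uhrf1 (log2 -0.33, SE 0.10, adjusted p = 0.31). The general pluripotency, primitive endoderm and p53 lists had a median and a mean of opposite sign, as did the 2-cell-like list, whose median was -0.14, mean 0.10 and camera direction down. The S2TG methylation list had a median of 0 and a mean of -0.06. In M2TG the median of the LIF-STAT3 list was -0.03 and camera's direction up, and the medians of the Nodal-Activin and housekeeping lists were each 0.01 with camera's direction down.

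**Figure D3:**
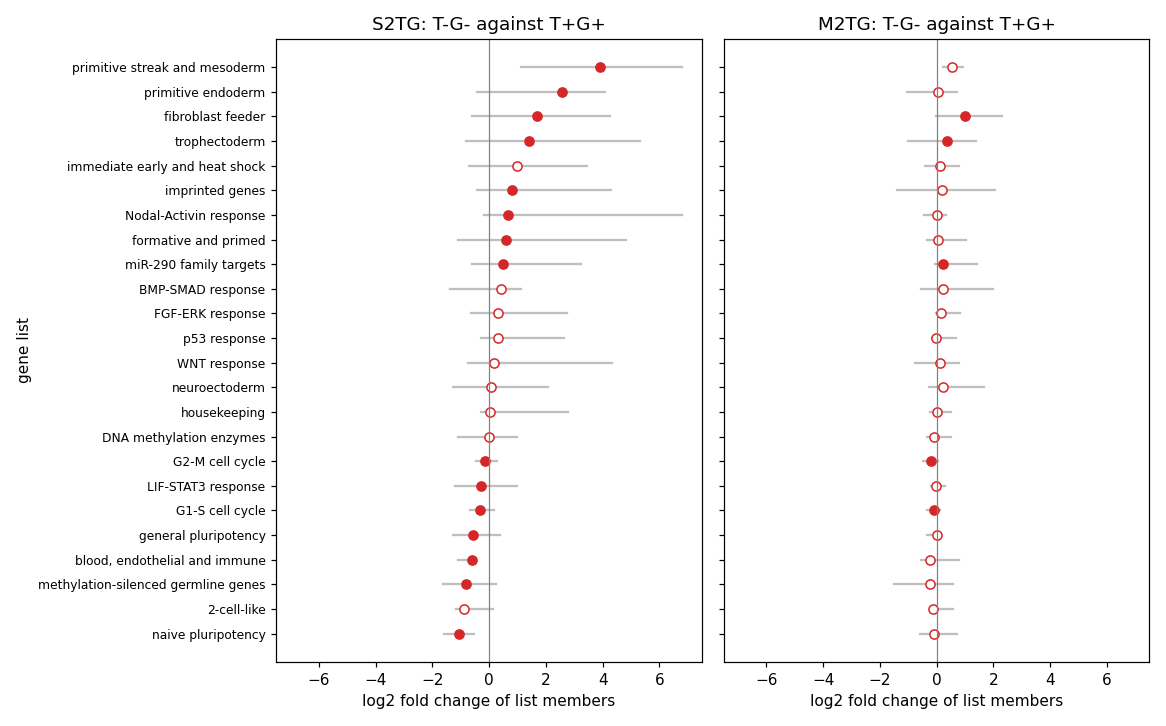
Median log2 fold change of each gene list in T-G- against T+G+ cells of S2TG and M2TG. Dots are list medians, filled where the camera adjusted p passed 0.05 with the preset correlation of 0.01 and open where it did not. Grey lines run from the lowest to the highest member. With the preset correlation 15 lists passed in S2TG (8 higher, 7 lower) and 5 in M2TG (3 higher, 2 lower). With an estimated correlation no list passed in either line.

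At the miR-290 locus the tagged line showed the following levels. The entry taken by its name as the primary transcript of the cluster was at 11.9 ± 3.64 CPM in T+G+, 10.1 ± 6.5 CPM in T+G-, 8.18 ± 6.36 CPM in T-G+ and 5.82 ± 5.31 CPM in T-G- cells of M2TG. T-G- against T+G+ did not pass (log2 -1.04, SE 0.64, adjusted p = 0.954; log2 -1.79 without T-G- replicate 1) unless the replicate number was a block (block log2 -1.19, block adjusted p = 0.0193). AU018091 (chromosome 7, 3154658 to 3169203), an annotated neighbour, was at 146 ± 30 CPM in T+G+, 187 ± 43.3 CPM in T+G-, 215 ± 35.8 CPM in T-G+ and 242 ± 67.1 CPM in T-G- cells (T-G- against T+G+ log2 0.73, SE 0.21, adjusted p = 0.302; block log2 0.71, block adjusted p = 3.127e-14). Myadm (chromosome 7, 3289080 to 3300442; log2 0.25) and Nlrp12 (3218784 to 3249740; log2 0.66) did not pass, and with the block Myadm rose (block log2 0.25, block adjusted p = 4.781e-05) and Nlrp12 did not pass.

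In M2TG few entries separated gates with at least 1 reporter on without the replicate block, and up to 311 did with it. T+G- against T-G+ and T+G- against T+G+ each called eGFP alone, and T-G+ against T+G+ called 0 of 13445 entries (edgeR). Unadjusted p was under 0.05 for 98, 132 and 149 entries. DESeq2 called 11, 0 and 2, the last being tdTomato and 9530068E07Rik. The replicate block called 17, 203 and 311 entries. The T+G- against T-G+ count was 0 without T+G- replicate 2, 3 or 4 or T-G+ replicate 2, 3 or 4 and 2 without T-G+ replicate 1. The T+G- against T+G+ count was 0 without any 1 T+G+ library or T+G- replicate 2, 3 or 4. T-G+ against T+G+ called tdTomato without T-G+ replicate 1. With the block, and named after their values were seen, the collagen gene Col8a1 (block log2 -2.16, block adjusted p = 0.00875) and Prrx1, a mesenchymal transcription factor (block log2 -2.40, block adjusted p = 0.0117), were lower in T+G- than in T-G+ cells. Against T+G+ cells, the X-linked gene Xlr3a was lower in T+G- and T-G+ cells (block log2 -1.33 and -1.19), while AU018091 (block log2 0.35 and 0.56) and the receptor Fgfr2 (block log2 0.78 and 0.86) were higher in both. Of the lists, fibroblast genes were lower in T+G- than in T-G+ cells (median log2 -1.14, adjusted p = 2.3e-92; adjusted p = 0.000227 with an estimated correlation, 0.0156 with the block as well). There were 15 falls adjusted over the list alone. They were higher in T-G+ than in T+G+ cells (median log2 0.97, adjusted p = 3.669e-28; adjusted p = 0.0374 with an estimated correlation, 0.5 with the block as well). They were lower in T+G- than in T+G+ cells (median log2 -0.44, adjusted p = 2.524e-11; adjusted p = 0.299 with an estimated correlation). Tagln was at 8.03 ± 2.17 CPM in T+G- and 17.1 ± 7.68 CPM in T-G+ cells. Primitive endoderm genes were lower in T+G- cells, against T-G+ (adjusted p = 0.000935; adjusted p = 0.292 with an estimated correlation) and against T+G+ (adjusted p = 5.384e-05; adjusted p = 0.279 with an estimated correlation). G2-M genes were lower in T-G+ than in T+G+ cells (adjusted p = 0.0133; adjusted p = 0.953 with an estimated correlation). The block added 2-cell-like genes, higher in T+G- than in T-G+ cells (adjusted p = 0.0152), and G2-M genes, lower in T+G- than in T+G+ cells (adjusted p = 0.00204). Both calls were lost with the block and an estimated correlation (adjusted p = 0.979 and 0.849). No other list passed in these 3 comparisons, and no member of the lists named here passed over all genes without the block (edgeR).

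The parental share of transcripts at the tagged locus separated the gates with 1 reporter on. In S2TG, genome1 gave 26.3% ± 6.8 of the allele-assigned Sox2 counts in T+G- cells and 59.5% ± 7.6 in T-G+ cells, a difference of -33.2 percentage points (2-sided exact permutation test, n = 4 and 4, p = 0.0286, the smallest that 70 regroupings allow). The share was 48.2% ± 2.2 in T+G+ and 31.3% ± 3.5 in T-G- cells. In M2TG, whose reporters are named for the other super-enhancer, the 4 gates lay at 39.7% ± 0.8, 40% ± 2.9, 40.4% ± 1.7 and 39.4% ± 1.5 and the difference was -0.4 points (exact p = 0.886). For the miR-290 entry in M2TG, genome1 gave 15.9% ± 10.5 in T+G- and 66% ± 8.9 in T-G+ cells, a difference of -50.1 points (exact p = 0.0286). The share was 40.6% ± 6.1 in T+G+ and 28.1% ± 6 in T-G- cells. In S2TG the difference was 1.4 points (exact p = 0.914). AU018091 went the other way from the miR-290 entry in M2TG, with 61.2% ± 3.6 genome1 in T+G- and 37.9% ± 4 in T-G+ cells, a difference of 23.3 points (exact p = 0.0286), against -0.6 points in S2TG (exact p = 0.657). Myadm differed by 10.4 points in M2TG (exact p = 0.0286) and by -4.5 points in S2TG (exact p = 0.143). The Benjamini-Hochberg adjusted p of each exact test at p = 0.0286 was 0.0571, both over the 4 planned tests and over the 8 with at least 20 allele-assigned counts per library. The AU018091 and Myadm shares were added after the values were seen. Nlrp12, at 11 and 6.9 counts per library in S2TG and M2TG, was left out of this adjustment and differed by -2.3 and 43.8 points (exact p = 0.714 and 0.0286). In each difference at exact p = 0.0286, all 4 T+G- libraries lay on 1 side of all 4 T-G+ libraries. A paired sign-flip test of 4 pairs cannot go below 0.125, the value it gave for each difference with the smallest exact p. Sox2 had 592 allele-assigned counts per library on average in S2TG and 1061 in M2TG, the miR-290 entry 36.5 and 63.4. In the M2TG T+G- replicate 2 library the miR-290 share was 4% of 50 counts (95% Clopper-Pearson interval 0.5 to 13.7%, which covers counting error only).

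**Figure D4:**
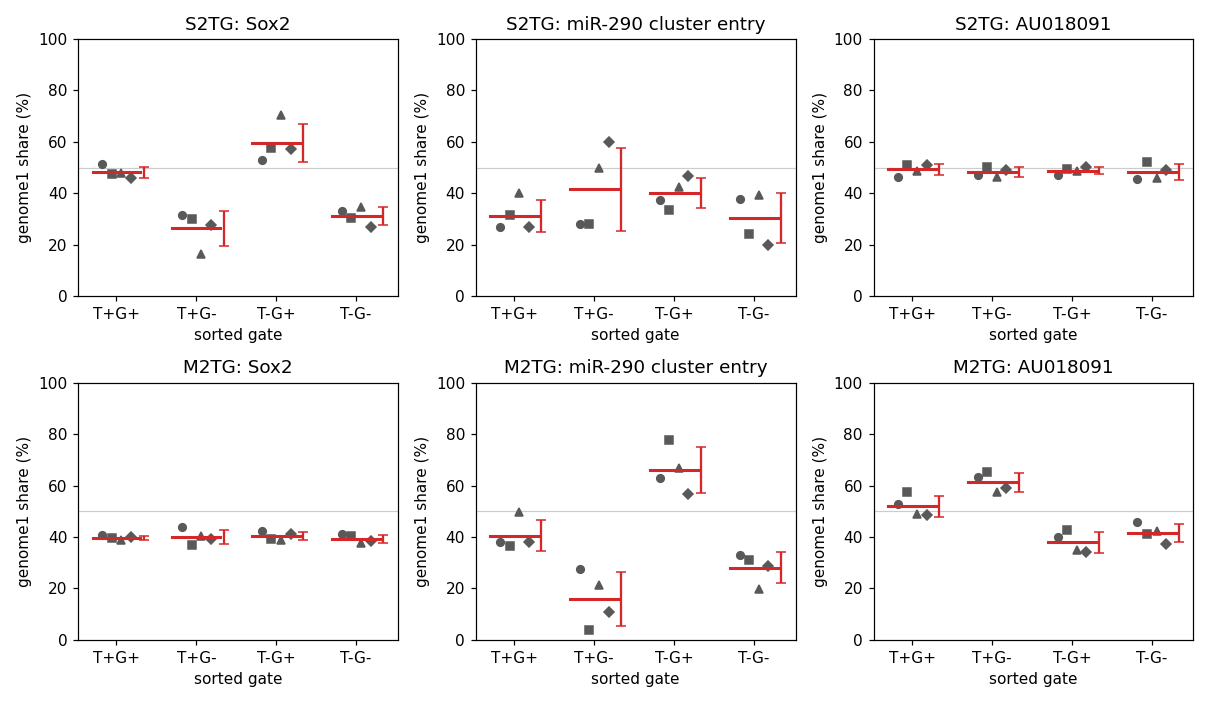
Genome1 share of allele-assigned counts in percent for Sox2 and the miR-290 entry in the 4 gates of each line. Markers are replicates 1 to 4 (circle, square, triangle, diamond), the red line is the gate mean and the red bar its SD; Sox2 differs by -33.2 points between T+G- and T-G+ in S2TG and the miR-290 entry by -50.1 points in M2TG.

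A test of this allelic difference across all genes called 2 genes in each line, and of 35 splits 3 in S2TG and 2 in M2TG called as many, the others parting at most 2 of the replicate numbers. In S2TG these were Sox2 (log2 ratio -2.07, SE 0.26, edgeR adjusted p = 0.0283) and Polr2e, an RNA polymerase subunit gene on chromosome 10 (80035949 to 80039795; log2 ratio -0.74, SE 0.14, adjusted p = 0.0283; 39.2% ± 5.84 genome1 in T+G- and 51.5% ± 2.23 in T-G+ cells), of 9276 genes tested. With the replicate block Sox2 did not pass (adjusted p = 0.0881), while Polr2e (adjusted p = 0.000357), the ribosomal gene Rpl35a (log2 ratio -0.54, adjusted p = 0.0235) and the deubiquitinase Usp1 (log2 ratio -0.55, adjusted p = 0.0329) did. The S2TG count was 0 without T+G- replicate 1, T+G- replicate 2, T-G+ replicate 2 or T-G+ replicate 4. It was 1 without T-G+ replicate 1 or 3, and 4 without T+G- replicate 3 or 4. In M2TG, of 9558 genes, the calls were AU018091 (log2 ratio 1.41, SE 0.13, adjusted p = 6.714e-06) and the miR-290 entry (log2 ratio -2.91, SE 0.36, adjusted p = 1.569e-05). The block added the collagen genes Col6a3 (log2 ratio 3.73, adjusted p = 0.000332) and Col6a1, the second named after its values were seen, and the secreted phosphoprotein gene Spp1 (log2 ratio 0.25, adjusted p = 1.472e-05), for 5 in all. Col6a3 was at 54.6% ± 21.4 genome1 in T+G- and 9.53% ± 10.8 in T-G+ cells. The fibroblast list was also higher in T-G+ than in T+G- cells of M2TG. For the collagen genes, feeder reads of 1 genome therefore cannot be told apart from a change of allele use. Of the imprinted genes, 14 were tested in S2TG and 12 in M2TG and 0 passed in either (edgeR, with or without the block). At an unadjusted p under 0.05 there were 340 genes in S2TG and 268 in M2TG.

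The response of T-G- against T+G+ cells differed between the lines at some genes. Krt8 (log2 1.40 in M2TG against 5.29 in S2TG; difference -3.90, SE 0.86, adjusted p = 0.0318) and Krt7 (0.14 against 2.48; difference -2.34, SE 0.42, adjusted p = 0.0215) changed less in M2TG. So did the kinase genes Itpkb (difference -3.31, SE 0.77, adjusted p = 0.0424) and Nuak1 (difference -2.56, SE 0.55, adjusted p = 0.0295) and the interferon-induced GTPase Irgm2 (difference -2.99, SE 0.68, adjusted p = 0.0367). In the other direction stood Dppa3 (log2 0.73 in M2TG against -1.25 in S2TG; difference 1.98, SE 0.39, adjusted p = 0.0287), the cytokine Osm (difference 2.47, SE 0.62, adjusted p = 0.0493), Lrrc31 (difference 2.15, SE 0.54, adjusted p = 0.049), Ddc (difference 1.58, SE 0.39, adjusted p = 0.0481) and Dnajc6 (difference 1.40, SE 0.34, adjusted p = 0.0481). In all, 128 of 13714 entries differed, 35 with M2TG above S2TG and 93 with M2TG below, and 2114 had an unadjusted p under 0.05 (edgeR, all 32 libraries). This line difference of double negative vs double positive genes (T-G- against T+G+) gave 3895 entries with the replicate block and 534 with DESeq2, and 11 of 100 regroupings called as many as 128. The library kit differs between the lines and cannot be told apart from them. The count was 1524, 227, 13 and 0 without S2TG T-G- replicates 1, 2, 3 and 4. It was 54, 22, 31 and 6 without S2TG T+G+ replicates 1 to 4, 61, 3 and 1 without M2TG T+G+ replicates 1, 3 and 4, and 7, 31 and 0 without M2TG T-G- replicates 1, 3 and 4. Across 12799 genes tested in both lines the log2 changes had a Pearson r of 0.49 and a Spearman rho of 0.37, where genes are not independent replicates. Of the calls, 1 gene was higher in both lines, against 1.1 for independent lists, and 5 were lower in both, against 0.4, the reporters included. With the block, 773 were higher in both, against 377.1, and 830 lower in both, against 344.3, and 128 and 185 went in opposite directions, against 369.9 and 351.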

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

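The tests of added reads at fibroblast list members and of swaps within replicate numbers were chosen after the results they bear on were seen; the other tests in this part were written beforehand.

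In groups of 4 libraries, 9 of 56 sets held a library far from the other 3 by Dixon's criterion, where chance gives about 1 in 20. M2TG replicate 1 carried reporter transcripts in gates sorted without that reporter. There tdTomato was at 86.46 CPM in T-G+ replicate 1 (others 5.61 to 9.71) and at 30.59 CPM in T-G- replicate 1 (others 3.69 to 6.86). In the same replicate eGFP was at 20.53 CPM in T+G- replicate 1 (others 2.47 to 4.77) and at 18.94 CPM in T-G- replicate 1 (others 1.58 to 3.83). In M2TG T+G+ replicate 2, eGFP was at 446.67 CPM (others 289.23 to 310.19). The genome1 share of the miR-290 entry was 49.6% in M2TG T+G+ replicate 3 (others 36.5 to 38.2%). Total counts in M (mega) were 14.94 M in S2TG T+G+ replicate 3 (others 5.83 to 6.64), 8.91 M in S2TG T-G+ replicate 3 (others 5.63 to 6.05) and 8.64 M in M2TG T-G- replicate 2 (others 7.31 to 7.51).

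The T-G- against T+G+ change differed between the lines at 128 entries by the test of the difference itself. Chance was not excluded: 11 of 100 drawn regroupings of these libraries, the real one included, called as many, and the highest other regrouping called 1654, several times 128. The regroupings were drawn without regard to replicate numbers. The S2TG T-G- libraries were not alike. On the first principal component replicate 1 lay at -16.5 and replicates 2, 3 and 4 at 41.6, 91 and 91.9, with the other gates between -28.6 and 2.4. Whether this gave the higher counts of some regroupings was not tested.

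The first pattern is the set of 2283 entries that separated T-G- from T+G+ cells in S2TG. Chance was not excluded, since 2 of the 35 splits called as many: the highest other, at 2582, parted 2 of the replicate numbers and grouped T-G- replicate 1 with T+G+ libraries, and of the 8 splits that part all 4 numbers the highest other called 1247. With the replicate block 1 of 8 swaps within numbers, the real one, called as many (6021, highest other 4608), too few for a share under 0.05. Carry-over of feeder fibroblasts as the whole cause is argued against if feeders carry no CAST genome, since feeders need reads of nearly 1 genome. Reads added in T-G- libraries at 1090 genes that rose were 48.8% genome1 in the median (95% interval 48.1 to 49.5%). At 16 fibroblast list members they were 43.1% genome1 (30.4 to 54.9%). These intervals resample genes after averaging the libraries of each gate, so they hold no spread between libraries. A difference between replicate numbers alone is argued against, since each number is in each gate once and the block kept all 2283. A difference of cell state between the gates stays open. The naive pluripotency list (12 of 18 lower, 0 higher) and the streak list (6 of 7 higher) moved as such a difference would give. Both lists were read in these same libraries, and camera lost both calls with an estimated correlation. Cell state was not tested apart from such lists.

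The second pattern is the rise of the fibroblast list in M2TG T-G- cells, of which 24 of 31 genes were expressed enough to be tested. Reads added at 16 list members were 7.6% genome1 in the median, as feeders of 1 parental type would give, but the 95% interval of 0.5 to 33.3% leaves it undecided. Feeder carry-over past the gelatin plating and the sort may therefore account for the rise of this list. Fstl1 was at 149, Col1a1 at 30.9 and Tagln at 30.8 CPM in T-G- against 92.4, 12.8 and 7.13 CPM in T+G+ cells. At 7 of the genes that rose over all genes the share was 53.8% (44.6 to 67.2%), where feeders need reads of nearly 1 genome. If feeders carry no CAST genome, this argues against them as the whole cause at these 7 genes. The upper end of the interval passes the range set beforehand for that verdict. Both intervals here also resample genes and hold no spread between libraries. Of the 35 splits 1, the real one, gave the 17 calls over all genes and the highest other gave 0, but only 8 splits part all 4 replicate numbers, too few for a share under 0.05. The same holds with the block, where 1 of 8 swaps called as many (3185, highest other 5), and a difference of stem cell state between the gates was not tested.

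Without the replicate block, the remaining gate counts hold only the reporters the cells were sorted on, so the splits say nothing there about other genes. For T+G- against T-G+ (2 in S2TG, 1 in M2TG) and T+G- against T+G+ (1 in each line), 1 of 35 splits gave the count and the highest other gave 0. For T-G+ against T+G+ in S2TG (1), 2 of 35 splits did and the highest other gave 1, and in M2TG (0) all 35 did, with 0 in the highest other. Chance was not excluded for the allelic counts of 2 in S2TG (3 of 35 splits, highest other 3) and in M2TG (2 of 35 splits, highest other 3). Of the 8 splits that part all 4 replicate numbers, the real one had 2 allelic calls and the highest other 0 in each line, too few splits for a share under 0.05, and the splits with 3 part 0 or 2 numbers.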

How the results depend on the processing

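Fits without the reporter entries, without chromosome 6 or 8, without a whole replicate number or with the block plus another setting, and all AU018091 shares, were added after seeing the data. T-G- cells are called double negative, T+G+ double positive, T+G- T only and T-G+ G only. Of 1611 alternative values 1214 kept direction and side of the threshold or stayed within 1.5 times. Of the rest 250 lost a call, 16 gained one, 122 moved and 9 reversed. The cause was not tested except where named. The S2TG double negative vs double positive genes (2283) were 1066 with at least 1 on the log2 scale, 1056 and 924 with genome1 and genome2 reads only, 6021 with the replicate block, 3 with the feeder score as a covariate, 3 with only the 8 libraries compared and 2 to 4954 leaving out libraries. The S2TG double negative vs double positive genes with replicate block (6021) became 9 with the feeder score, 2673 and 2822 with genome1 and genome2 reads, and 1078 to 7319 without a number. The S2TG gene lists double negative vs double positive (15) became 0 with an estimated correlation and 14 to 16 leaving out libraries. The S2TG T only vs G only genes (2), T only vs double positive genes (1) and G only vs double positive genes (1) each became 0 with genome1 reads, with genome2 reads and with the reporters left out (by construction, the calls being reporters). They were 2, 1 and 1 without any 1 library, and the block gave 2 for T only vs double positive. The Sox2 log2 fold change S2TG double negative vs double positive (-1.27) was -0.84 with genome2 reads, -0.76 with the feeder score and -1.68 to -1.04 leaving out libraries. The S2TG allelic difference T only vs G only genes (2) were 1 at 100 allele counts, 1 with DESeq2 and 0 to 4 leaving out libraries. The Sox2 genome1 share S2TG T only minus G only (-33.2) was -33.72 from FPKM and -35.41 to -29.57 leaving out libraries, with a sign-flip p of 0.125, the smallest 4 pairs allow. With 1 library left out, the exact test of a share cannot go below 0.0571, so its calls end by construction. The miR-290 locus genome1 share S2TG T only minus G only (1.446) was 1.263 from FPKM and reversed to -1.395, -4.728 and -0.7865 leaving out libraries (-4.728 to 5.969). The M2TG double negative vs double positive genes (17) were 10 with at least 1 on the log2 scale, 124 with DESeq2, 2 and 2 with genome1 and genome2 reads, 3185 with the block, 1 with the 8 libraries, 8 with all 32 and 1 to 37 leaving out libraries. The M2TG double negative vs double positive genes with replicate block (3185) became 1416 with the feeder score, 959 and 1064 with genome1 and genome2 reads, and 2237 to 2765 without a number. The M2TG gene lists double negative vs double positive (5) were 0 with an estimated correlation, 0 with fry, 9 with the block, 3 with the feeder score and 3 to 6 leaving out libraries. The M2TG T only vs G only genes (1) were 11 with DESeq2, 0 and 0 with genome1 and genome2 reads, 17 with the block, 0 without reporters (by construction), 0 with the 8 libraries, 2 with all 32 and 0 to 2 leaving out libraries. The M2TG T only vs double positive genes (1) were 0 with DESeq2, 0 and 0 with genome1 and genome2 reads, 203 with the block (68 to 174 without a number), 0 without reporters, 0 with the 8 libraries and 0 to 1 leaving out libraries. The M2TG G only vs double positive genes (0) were 2 with DESeq2, 311 with the block (83 to 208 without a number), 1 with all 32 libraries and 0 to 1 leaving out libraries. The Sox2 log2 fold change M2TG double negative vs double positive (0.04) reversed to -0.26 with the feeder score and to -0.01, -0.02 and -0.09 leaving out libraries (-0.09 to 0.16). The M2TG allelic difference T only vs G only genes (2) were 1 at 100 allele counts, 5 with the block and 2 to 3 leaving out libraries. The Sox2 genome1 share M2TG T only minus G only (-0.3881) was -0.4648 from FPKM and reversed to 0.695 and 0.2428 leaving out libraries (-1.613 to 0.695). The miR-290 locus genome1 share M2TG T only minus G only (-50.07) was -51.72 from FPKM and -53.99 to -46.11 leaving out libraries, with a sign-flip p of 0.125. The AU018091 genome1 share M2TG T only minus G only (23.31) was 23.04 from FPKM and 21.98 to 24.89 leaving out libraries, with a sign-flip p of 0.125. The line difference of double negative vs double positive genes (128) was 534 with DESeq2, 50 with no filter, 31 and 21 with genome1 and genome2 reads, 3895 with the block and 0 to 1524 leaving out libraries. The block also changed calls of list members, whose numbers stand beside each list for T-G- against T+G+. Fewer allele-assigned counts limit the fits on genome1 or genome2 reads, and depth limits the miR-290 shares, at 36.5 and 63.4 such counts per library.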

Other observations

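The tests of copy gain and of a general chromosome 7 shift in this part were chosen after the values were seen; the test of miR-290 family sites was written beforehand.

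Loss of a microRNA would raise transcripts that carry its sites, and the miR-290 family shares 1 seed. In M2TG, 2306 genes with a 7-base match to the seed in the 3' UTR changed by 0.028 more on the log2 scale, in the median, from T+G+ to T-G- cells than genes without one matched on UTR length and expression (12183 genes with a UTR, 90.6% of those tested). Of 100 shuffled 7-base words 3 gave as much, and their 95th percentile was 0.023. A slightly lower activity of the family in M2TG T-G- cells would give such a rise, though the shift is small and other differences between these genes stay open. Feeder reads, which may account for the rise of the fibroblast list in this contrast, were not separated from it. The shuffled words measure a spread over words and not over libraries. In S2TG the difference was -0.062 over 2277 genes with a site, and 100 of 100 shuffled words gave as much or more. This is not the rise that lower activity predicts, though 8 of the 18 listed targets rose. A value below every shuffled word may mean that genes with a site differed in other ways, which could hide a small rise. The activity of the family in S2TG therefore stays open.

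A pair of replicate numbers showed shifted parental shares over a whole chromosome in every gate. In S2TG replicate 3, genome1 gave 31.6 to 32% of the allele-assigned chromosome 6 counts, against 47.5 to 48.3% in the other replicates. Chromosome 6 genes were higher by 0.57 on the log2 scale in the median (0.55 to 0.59 over the gates) than in the other replicates. An extra genome2 copy of chromosome 6 is a candidate explanation, since a shift between parental copies alone would leave the total in place. In M2TG replicate 4, genome1 gave 55.9 to 60.5% of the chromosome 8 counts, against 48.9 to 51.9%, and chromosome 8 genes were higher by 0.28 (0.21 to 0.33). The share in replicate 4 was 55.9% in T+G+, 58% in T+G-, 58.5% in T-G+ and 60.5% in T-G- cells. The log2 difference rose in the same order, so in this replicate the shift cannot be told apart from the gates at chromosome 8 genes. An extra genome1 copy in part of the cells may be present. Without chromosome 6 genes, T-G- against T+G+ in S2TG gave 2387 calls, within 1.5 times of the 2283 with them. The chromosome 6 shift was alike in every gate, so this count says little about a difference between gates. The M2TG count without chromosome 8 genes is not given here, so the weight of that shift in the M2TG calls stays open.

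The opposite allele shifts of AU018091 and the miR-290 entry in M2TG were not shared by chromosome 7: the median T+G- minus T-G+ difference of its other tested genes was 0.5 percentage points.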
